A study of Mus musculus with 46 samples.

How the data were processed

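RNA sequencing had been performed on 46 libraries from 23 glioma-bearing mice. Microglia (MG) and macrophages of bone marrow origin (BMDM) had been sorted from the tumour of each mouse. Per the labels' protocols, MG were sorted as CD45+CD11b+Ly6C-Ly6G-CD49d- cells and BMDM as the matching CD49d+ cells, total RNA was taken from the sorted cells and libraries were made with a Smart-Seq kit, a full-length cDNA amplification without molecular identifiers. The deposited table held raw counts of reads per gene for 23329 mouse gene symbols, whole numbers with no normalization, and all 46 columns were used. Per the submitters' processing notes, CASAVA 1.8, STAR 2.5.0e, HTSeq and DESeq2 were used with the mm10 build. The annotation and the strand setting behind the counts were not given in the sources used here, so reads of overlapping or antisense genes and of close paralogs cannot be told apart. No count had been recorded in any library for 1535 of the symbols.

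The total count per library ran from 3007379 to 16993474. Intervals and floors cover counting error only, because amplified reads without molecular identifiers are not independent molecules. A fold against a group without any count was computed against a floor of 3 counts over the group and is given as at least that fold, and no fold is given where a group held 1 to 3 counts. No pair of libraries of one group was a duplicate: the smallest chi-square per degree of freedom between replicates was 10.7.

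Groups were taken from the stage and the cell type in the labels, and replicates are separate mice, named by number. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, robust dispersion and the filterByExpr filter (minimum count 10, minimum total 15), with 1 fit for the 23 MG libraries, 1 for the 23 BMDM libraries and 1 over all 46 for comparisons between the populations. After the filter 14534 genes in MG, 14568 in BMDM and 15901 in the joint fit were tested, which held 99.95%, 99.96% and 99.98% of the counts. The common biological coefficient of variation was 0.484, 0.651 and 0.589, with 16, 16 and 32 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison and a gene passed at an adjusted p of 0.05. In all, 33 comparisons were made: MG against BMDM in vehicle, each treatment against vehicle, recurrence against 5 days, the combination against each single treatment, and the difference between the populations in their response. Per-library levels are log2 CPM, scaled to TMM-adjusted library totals, with a prior count of 1.

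Gene lists were tested with camera, preset correlation 0.01, and again with an estimated correlation and with fry. Of 30 lists, 29 could be tested, in 957 tests over the 33 comparisons. They covered identity markers of MG and of blood-derived macrophages, states of macrophages such as antigen presentation and cell division, and markers of other cell types that the gate or the tissue could hold. Of their 442 genes, 431 were found by symbol and 6 by a synonym. The distance between the populations in each mouse, called the identity gap, is the MG minus BMDM difference of the mean microglia list level minus that of the blood-derived macrophage list, and was compared between stages by a two-sided exact permutation test.

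Genes are named by a rule. Among genes that passed, with a group mean of at least 3 log2 CPM and no overlap between the libraries of the compared groups, the 6 largest rises and falls were taken in MG against BMDM and in comparisons with vehicle, and the 3 largest of each elsewhere. To these were added up to 4 members that passed from each described list, or up to 2 of the smallest p where none passed. Csf1r, Itga4, Cdkn1a, Mki67, Igf1, Arg1 and Mrc1 were followed throughout, and Cdkn2a, Ptprc, Itgam, Ly6c2, Xist and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty served as checks, while Ly6g, also meant as a check, was not in the table. Predicted genes, clone-named genes, pseudogenes, ribosomal protein and mitochondrial genes and immunoglobulin or T cell receptor segments were left out, and some of the genes so chosen are not printed. The lists, this rule, the comparisons, the tests and the settings named next were fixed before the data were examined. Lars2, Malat1, Rn45s and the choroid plexus markers were chosen after their values were seen.

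Other settings were DESeq2 1.42.0, size factors by the relative log expression (RLE) method, no low-count filter, 1 fit over all libraries, a term for the style of the mouse number (short or long numbers), the mouse as a replicate block and leaving out each library in turn. A further 4 were chosen after seeing the data: leaving out 6 doubted libraries (fewer than 11000 genes with 10 or more counts, or both libraries of a mouse whose sex-linked genes did not match), a term for the sex-linked profile, a term for the Malat1 minus Lars2 level, and vehicle libraries of like Lars2 level. Where leaving out a library left 1 in its group, that library was assumed to vary like those of the other groups. This also holds for 5-day IR without the doubted libraries, with counts resting on the treated mouse 65972 alone.

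Mouse numbers pair libraries of the same animal, per the labels. As a check of this pairing, deviations of both libraries from their group means were correlated across genes in each mouse, which gave r from -0.094 to 0.442 with a median of 0.153, above 0.1 in 13 of 23 mice.

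The test was tested on simulated data, with 200 genes changed by known folds in counts drawn from the real means and library sizes. In the simulation of MG against BMDM in vehicle, on 15277 genes, 0.990% of the calls were false and 11.9%, 58.2% and 80.3% of genes changed 2-fold, 4-fold and 8-fold were recovered. For recurrent BLZ945 against vehicle in BMDM, the same shares were 1.96%, 0%, 28.4% and 47.0% on 14109 genes. Coordinates are those of the RefSeq annotation of GRCm38.p6, the assembly of the mm10 build.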

Results

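Gliomas had been induced in nTVA mice lacking both copies of Ink4a/Arf by intracranial injection of DF1 cells, a chicken fibroblast line that produces the RCAS-PDGFB-HA retrovirus. The series asked how tumour-associated microglia (MG), the resident macrophages of the brain, and bone marrow-derived macrophages (BMDM) respond to therapy while tumours regress and after they regrow. Treatments were BLZ945, a small-molecule inhibitor of the CSF1 receptor, radiation (IR), and both together. MG and BMDM were sorted from the same 23 mice: 4 given vehicle, 4 taken after 5 days of BLZ945, 2 after 5 days of IR, 3 after 5 days of IR+BLZ945, and recurrent tumours of 2 mice after BLZ945, 4 after IR and 4 after IR+BLZ945. Total counts were 3007379 in MG of the 5-day IR+BLZ945 mouse 65971, 4597962 in MG of the recurrent IR mouse 68344 and at least 7771613 in the other 44. Below, the value after a gene is its log2 fold change ± SE from edgeR's quasi-likelihood test, with the Benjamini-Hochberg adjusted p. Gene lists have a Benjamini-Hochberg FDR from camera, and levels are log2 CPM, mean ± SD.

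Cdkn2a, which encodes the deleted Ink4a and Arf proteins, lay at group means between -2.79 and 0.69. In vehicle mice Ptprc, which encodes CD45, stood at 8.93 in MG and 9.76 in BMDM, and Itgam, which encodes CD11b, at 11.07 and 9.16. Ly6c2, a gene of the excluded Ly6C antigen, stood at -1.25 and 2.02. Xist and the Y-linked genes gave matching profiles in both libraries of 22 mice, 11 with Xist and 11 with Y-linked expression. In the 5-day IR mouse 65698, MG had the Xist profile and BMDM the Y-linked one. This mouse's libraries and 4 of few detected genes (BMDM of 122 and 124, MG of 65971 and 68344) are called doubted.

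Levels of Lars2 (chromosome 9, 123366927 to 123462675), a mitochondrial leucyl-tRNA synthetase gene, and Malat1 (chromosome 19, 5795690 to 5802672), a nuclear noncoding RNA, moved with the stage in both populations. Lars2 in MG stood at 9.76 ± 3.81 in vehicle, with a range of 6.15 to 13.87, and at 13.19, 11.89 and 13.97 in recurrence after BLZ945, IR and IR+BLZ945. In BMDM it stood at 6.12 ± 2.20 in vehicle and at 12.53, 12.03 and 12.30 in recurrence. Malat1 was 9.59 ± 0.60 in vehicle MG and 9.22, 8.21 and 8.88 in recurrent MG, against 11.87 ± 0.89 in vehicle BMDM and 9.12, 8.29 and 9.38 in recurrent BMDM.

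**Figure D1:**
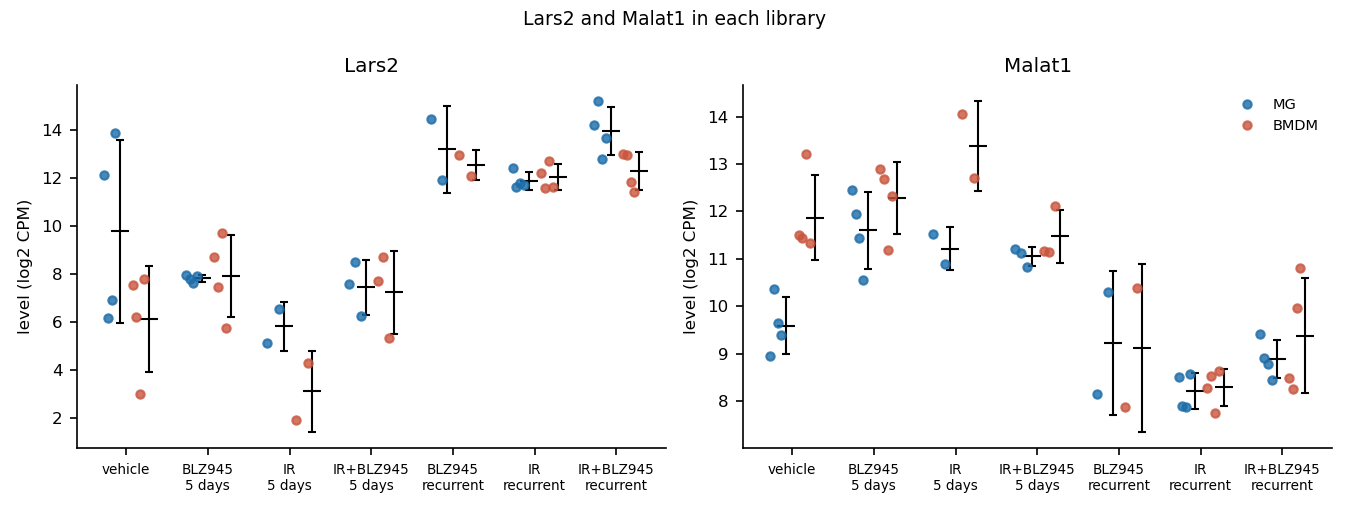
Lars2 and Malat1 levels (log2 CPM) of each of the 46 libraries by stage, MG and BMDM in separate colours.

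In vehicle tumours (4 mice), MG carried microglia identity genes and BMDM carried antigen presentation, dendritic cell and monocyte genes. Of 15901 genes, 611 were higher and 843 lower in MG than in BMDM. The largest rises included Gpr165 (6.99 ± 1.59, adjusted p = 0.00256), the matrix proteases Adamts16 (5.35 ± 1.20) and Adamts1 (5.22 ± 0.84, adjusted p = 2.99e-05), and Lox (5.32 ± 1.22), an enzyme that crosslinks collagen. The largest falls included the F4/80-related receptor Emr4 (-7.89 ± 1.22, adjusted p = 2.22e-05), the lectin receptor Cd209a (-7.18 ± 0.80, adjusted p = 1.16e-07) and Ccr7 (-7.13 ± 0.87), the lymph node homing receptor of dendritic cells. Itga4, which encodes the CD49d antigen used in the sort (chromosome 2, 79255426 to 79333114), was 1.97 ± 1.12 in MG and 7.10 ± 0.44 in BMDM (-4.88 ± 0.46, adjusted p = 3.81e-09), a difference the gate itself selects. Csf1r, the target of BLZ945 (chromosome 18, 61105572 to 61131139), was 12.86 ± 0.60 and 11.22 ± 0.15 (1.73 ± 0.28, adjusted p = 2.77e-05), and Mrc1, the mannose receptor, was lower in MG (-2.97 ± 0.67, adjusted p = 0.00237). Cdkn1a (-0.79, adjusted p = 0.116), Mki67 (0.51, adjusted p = 0.757), Igf1 (0.12) and Arg1 (-0.67) did not pass.

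Of 20 microglia identity genes, 18 were higher in MG and none lower (20 adjusted over the list alone, median 3.12, camera FDR = 2.99e-31), among them Sall3 (4.85 ± 0.89), Sall1 (4.81 ± 0.91), Gpr56 (4.50 ± 0.71) and Lag3 (4.41 ± 0.64). Of 22 blood-derived macrophage genes, 18 were lower (19 adjusted over the list alone, median -3.49, camera FDR = 2.28e-25), with Ccr2 (-5.01 ± 0.75), the receptor that draws monocytes into tissue, and Cd24a (-6.03 ± 1.03). All 10 MHC class II genes were lower in MG (10 adjusted over the list alone, median -4.49, camera FDR = 5.22e-23), including Ciita (-5.97 ± 0.86), their transactivator, and H2-Ab1 (-4.69 ± 0.65). Lower too were 7 of 10 dendritic cell genes (8 lower and 1 higher adjusted over the list alone, camera FDR = 2.78e-12), 8 of 18 alternative activation genes (12 lower and 1 higher, camera FDR = 3.42e-08) such as Clec10a (-5.75) and Ccl22 (-5.90 ± 0.91), and 6 of 10 border-associated macrophage genes (7, camera FDR = 9.45e-05). T and NK cell transcripts, which mark cells other than MG and BMDM, were lower in MG for 7 of 14 genes (13 adjusted over the list alone). Among them were Gzmb (-6.04) and Nkg7 (-5.95). The list had a camera FDR of 1.75e-05 and an adjusted p of 0.176 with an estimated correlation. The mouse as a block changed calls of the checkpoint list (camera FDR from 0.0398 to 0.0512) and the neutrophil list (from 0.067 to 0.0033). The 1454 genes became 2686 without the doubted libraries, 343 with the vehicle mice of like Lars2 level, 773 without mouse 41, 852 without 78 and 941 without 65967.

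After 5 days of BLZ945 (4 mice, 4 vehicle), MG had lower cell division and hypoxia and higher MHC class I lists by camera at its preset correlation. Chance was not excluded (3 of 35 splits of the libraries gave as many genes). In MG 30 genes rose and 14 fell among 14534. Rises included the protease inhibitor Spint1 (9.31 ± 1.16, adjusted p = 0.00098; levels of 7.07 to 7.55 in 3 mice and -0.45 in 65975), Wdfy1 (2.63 ± 0.47), Slamf8 (2.22 ± 0.43, adjusted p = 0.0364) and Malat1 (2.15 ± 0.43, adjusted p = 0.0418). Falls included the lectin Clec4n (-4.19 ± 0.87), the mitotic kinase Pbk (-3.26 ± 0.61), cyclin B1 (Ccnb1, -2.88 ± 0.54, adjusted p = 0.0339) and Lbh (-2.50 ± 0.36, adjusted p = 0.00534). Csf1r (0.15 ± 0.23, adjusted p = 0.844) and Mki67 (-2.28 ± 0.65, adjusted p = 0.108) did not pass. Of 26 cell cycle genes 1 fell (19 adjusted over the list alone, median -2.13, camera FDR = 2.41e-18). The MHC class I genes H2-T23 (2.11 ± 0.42) and H2-K1 (1.70 ± 0.35) rose among 12 (9 adjusted over the list alone, camera FDR = 1.21e-10). The hypoxia genes Adm (-4.11 ± 0.78) and Ndrg1 (-4.01 ± 0.83) fell among 20 (6 adjusted over the list alone, camera FDR = 1.89e-08). In the same MG the glioma and precursor list was lower (0 of 13 past the threshold, 5 adjusted over the list alone, camera FDR = 6.14e-07, mean -1.48 against 0.58), as were border-associated (1 of 10, 5 lower and 1 higher adjusted over the list alone, camera FDR = 0.000481) and Ly6C-high monocyte genes (0 of 7, 1, camera FDR = 0.00919). With an estimated correlation these had adjusted p = 0.135 each. In place of 44 genes, 556 passed by DESeq2, 454 without the doubted libraries, 3 with the number style term, 7 with the sex-linked profile term, 93 in one fit over all libraries, and 0 with the Malat1 minus Lars2 term or with vehicle libraries of like Lars2 level. Without single libraries the count was 1 (122, 123 or 124), 695 (65975, 245 higher and 450 lower), 10 (vehicle 41), 5 (vehicle 65966), 137 (vehicle 65967, 43 higher and 94 lower) or 2 (vehicle 78).

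BMDM after 5 days of BLZ945 had higher antigen presentation and dendritic cell transcripts and lower microglia, border-associated macrophage and matrix transcripts. Among 14568 genes 284 rose and 519 fell. The largest rises included the neurotrophic factor receptor Gfra2 (4.60 ± 1.33, adjusted p = 0.0456) and Nudt17 (3.09 ± 0.50, adjusted p = 0.00194). Falls included Dcun1d3 (-5.51 ± 1.13), the DNA end-joining gene Xrcc5 (-5.19 ± 0.92, adjusted p = 0.00311) and the endothelin receptor Ednrb (-4.90 ± 1.21). Csf1r fell from 11.22 ± 0.15 to 10.04 ± 0.45 (-1.12 ± 0.30, adjusted p = 0.0335). All 8 MHC class II genes that passed, of 10, rose (9 adjusted over the list alone, median 1.51, camera FDR = 1.35e-14), with H2-Ob (1.63 ± 0.22, adjusted p = 0.000404) and H2-Ab1 (1.57 ± 0.38), as did 8 of 12 MHC class I genes (10, camera FDR = 1.32e-13), with the peptide transporter Tap1 (1.74 ± 0.30) and Psmb9 (1.45 ± 0.29). Dendritic cell genes rose for 5 of 10 (6 adjusted over the list alone, camera FDR = 1.99e-06, adjusted p = 0.102 with an estimated correlation), including Zbtb46 (2.41 ± 0.55) and Cd209a (2.31 ± 0.63). Microglia genes fell for 10 of 20 (11 adjusted over the list alone, median -1.47, camera FDR = 1.47e-06, adjusted p = 0.17 with an estimated correlation), with the purinergic receptors P2ry12 (-2.76 ± 0.45, adjusted p = 0.00194) and P2ry13 (-2.62 ± 0.45). Border-associated macrophage genes fell for 6 of 10 (8 adjusted over the list alone, camera FDR = 5.97e-06, adjusted p = 0.0679 with an estimated correlation): Folr2 (-4.41 ± 0.75), Siglec1 (-3.52), Cd209f (at least 362-fold lower) and Lyve1 (at least 96.7-fold lower). Matrix genes fell for 4 of 21 (10 adjusted over the list alone, median -1.27, or -1.21 with bounds, camera FDR = 0.000633, adjusted p = 0.102 with an estimated correlation), with the collagenases Mmp2 (-4.63 ± 0.68) and Ctsk (at least 92.8-fold lower). Glioma and oligodendrocyte precursor markers, a sign of other cells, fell for 4 of 13 (5 adjusted over the list alone, camera FDR = 0.00906, adjusted p = 0.223 with an estimated correlation). The count of 803 became 369 without the doubted libraries and 532 without 122, 1650 without 65975, 497 without vehicle 41 and 462 without vehicle 65966.

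After 5 days of IR (2 mice, 4 vehicle), targets of p53 rose and cell cycle genes fell in MG. Phlda3 (chromosome 1, 135766085 to 135769134), a p53-induced repressor of Akt, rose by 5.57 ± 0.51 (adjusted p = 4.23e-06), the death receptor Eda2r by 5.21 ± 0.97 (adjusted p = 0.00536), Trp53inp1 by 3.09 ± 0.52 and Bbc3, the apoptosis inducer PUMA, by 2.76 ± 0.42. Cdkn1a (chromosome 17, 29090979 to 29100722), the cell cycle inhibitor p21, rose from 7.63 ± 0.24 to 11.40 ± 0.54 (3.82 ± 0.40, adjusted p = 3.25e-05). Of 24 p53 and DNA damage genes 9 rose and none fell (13 adjusted over the list alone, median 1.25, camera FDR = 3.09e-28). Of 26 cell cycle genes 20 fell (26 adjusted over the list alone, median -5.64, camera FDR = 4.32e-51), with Top2a (-8.39 ± 1.54, adjusted p = 0.00503) and Mki67 (-6.90 ± 1.16, adjusted p = 0.00241). Nek2 (at least 139-fold) and Esco2 (at least 73.4-fold), of mitosis and chromatid cohesion, were lower. The list averaged 5.52 ± 0.80 in vehicle and 0.60 ± 0.12 after IR. Hypoxia and glycolysis genes fell for 7 of 20 (11 adjusted over the list alone, median -1.91, camera FDR = 2.82e-12, adjusted p = 0.195 with an estimated correlation), with Adm (-5.38 ± 1.16), Ndrg1 (-4.36), Gapdh (-2.73 ± 0.50) and Tpi1 (-2.46). In all 32 genes rose and 257 fell. Without the doubted libraries 298 passed, and 74 with vehicle libraries of like Lars2 level. The count of 289 became 158 without vehicle 41, 862 without vehicle 65967, 137 without vehicle 78, 69 without 65698 and 15 without 65972.

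BMDM after 5 days of IR also had higher p53 targets and lower cell cycle transcripts. Phlda3 rose by 7.22 ± 0.88 (adjusted p = 8.1e-05), and Mcoln3 (7.30 ± 1.60) and the interleukin 12 subunit Il12b (3.86 ± 0.63, adjusted p = 0.00185) were other large rises. Of 24 p53 genes 8 rose (11 adjusted over the list alone, median 1.44, camera FDR = 4.28e-21), with Bbc3 (2.93 ± 0.53) and Cdkn1a (2.43 ± 0.34, adjusted p = 0.000301). Of 26 cell cycle genes 16 fell (24 adjusted over the list alone, median -4.29, camera FDR = 1.62e-39). Birc5 was at least 274-fold lower (adjusted p = 2.17e-07), Prc1 at least 266-fold (adjusted p = 1.09e-05) and Bub1b at least 202-fold, while Mki67 did not pass (-2.48 ± 0.98, adjusted p = 0.2). Mrc1 (2.75 ± 0.67, adjusted p = 0.0484) and the monocyte chemokine Ccl2 (3.66 ± 0.82) rose. Among signs of other cells, border-associated macrophage genes had 1 of 10 higher (8 adjusted over the list alone, median 2.84, camera FDR = 5.81e-09), at a mean of 7.98 against 4.69 in vehicle, while the B cell list stood at 0.60 against 3.33 and the neutrophil list at -1.23 against 2.09 (camera FDR = 0.205 and 0.103). The astrocyte list had 1 of 10 higher, Aldoc (2.68 ± 0.60; 1 adjusted over the list alone, camera FDR = 6.9e-05). In all 51 genes rose and 105 fell. Without the doubted libraries 249 passed. Leaving out 1 library gave 66 (vehicle 41), 81 (vehicle 65966), 907 (vehicle 65967), 64 (vehicle 78), 49 (65698) or 1150 (65972) in place of 156.

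After 5 days of IR+BLZ945 (3 mice, 4 vehicle), MG had lower cell cycle and microglia identity transcripts and higher p53 targets, with transcripts of other brain cells higher in the same libraries. In MG 1388 genes rose and 565 fell. Ttr (chromosome 18, 20664209 to 20674326), the transthyretin gene of the choroid plexus, rose by 12.61 ± 2.18 (adjusted p = 0.00206), with Enpp2 (8.60 ± 1.22) and Kl (7.19 ± 1.25). Phlda3 (5.27 ± 0.48, adjusted p = 5.28e-06), Eda2r (4.77 ± 0.92), Cdkn1a (2.72 ± 0.37, adjusted p = 0.000271) and Ccng1 (1.41 ± 0.23) were among 8 of 24 p53 genes that rose (8 adjusted over the list alone, median 0.36, camera FDR = 3.92e-05, adjusted p = 0.0668 with an estimated correlation). Cell cycle genes fell for 20 of 26 (24 adjusted over the list alone, median -4.06, camera FDR = 1.59e-30, adjusted p = 0.0668 with an estimated correlation), including Ccnb1 (-8.35 ± 0.93, adjusted p = 2.58e-05), Ube2c (-7.75 ± 1.07), Tk1 (-6.64 ± 0.87) and Mki67 (-3.29 ± 0.78, adjusted p = 0.0137), and Fam64a was at least 141-fold lower. Microglia genes fell for 12 of 20 (13 adjusted over the list alone, median -1.17, camera FDR = 1.1e-07, adjusted p = 0.223 with an estimated correlation), with Crybb1 (-3.16 ± 0.57), Siglech (-2.30 ± 0.39) and P2ry12 (-1.92 ± 0.38). Gpnmb (4.29 ± 0.83) and Apoe (2.05 ± 0.60), genes of lipid-laden macrophages, rose, and Csf1r did not pass (-0.66 ± 0.25, adjusted p = 0.0805). Astrocyte genes rose for 6 of 10 (8 adjusted over the list alone, median 3.86, camera FDR = 2.97e-05), with Gfap (4.34 ± 0.90) and Clu (4.57 ± 1.15), neuron genes for 5 of 9 (8, median 3.66, camera FDR = 2.19e-05), with Syn1 (4.22 ± 1.00) and Snap25 (3.66 ± 0.85), and myelin genes for 3 of 8 (5, median 1.91, camera FDR = 0.00576), with Mbp (2.91 ± 0.38). With an estimated correlation their adjusted p = 0.224, 0.104 and 0.0668. The count of 1953 was 1153 without the doubted libraries and 214 with vehicle libraries of like Lars2 level (37 higher and 177 lower). MG of 65971 (fewest counts) correlated with the other 2 treated MG at r = 0.428 and 0.359. Its p53 list stood at 3.68, below all vehicle MG (4.05 to 4.45), against 5.08 and 5.36. Of that list, its Phlda3 (6.74) and Eda2r (3.27) were the highest of the 3. Removing 1 library gave 1161 (65971), 382 (vehicle 41, 170 higher and 212 lower), 577 (vehicle 65966, 287 and 290) or 1227 (vehicle 78).

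BMDM after 5 days of IR+BLZ945 had higher p53 targets and lower microglia and cell cycle transcripts. Ttr held 6576 counts over the 3 treated libraries and 2 over the 4 vehicle libraries (adjusted p = 0.0158), and Enpp2 (10.18 ± 1.77) and Phlda3 (6.29 ± 0.83, adjusted p = 0.00127) rose. Of 24 p53 genes 6 rose (12 higher and 1 lower adjusted over the list alone, median 1.15, camera FDR = 1.68e-11), with Bbc3 (2.60 ± 0.49) and Cdkn1a (1.40 ± 0.31, adjusted p = 0.0375). Of 26 cell cycle genes 3 fell, Bub1b (-5.23 ± 1.18), Tk1 (-1.83 ± 0.37) and Birc5 (-1.72 ± 0.35), with 11 adjusted over the list alone, a median of -1.23, a camera FDR of 2.21e-15 and an adjusted p of 0.057 with an estimated correlation. Of 20 microglia genes P2ry12 (-3.13 ± 0.51, adjusted p = 0.00718) and Tmem119 (-2.77 ± 0.58) fell (7 adjusted over the list alone, camera FDR = 2.22e-11, adjusted p = 0.057 with an estimated correlation). Col14a1 (-6.69 ± 1.51) fell, and Csf1r did not pass (-1.31 ± 0.34, adjusted p = 0.0796). The astrocyte list had 1 of 10 higher, Clu (3.16 ± 0.53; 6 adjusted over the list alone, camera FDR = 4.12e-07), in libraries with a mean Ttr level of 6.52 ± 3.06. Dendritic cell genes had 2 of 10 higher (5 adjusted over the list alone, camera FDR = 8.34e-08, mean 7.42 against 5.76) and neuron genes 0 of 9 (6, camera FDR = 4.43e-05). With an estimated correlation these had adjusted p = 0.0603 and 0.0749. In all 49 genes rose and 34 fell. DESeq2 called 610 genes, and 824 passed without the doubted libraries. Leaving out 1 library gave 17 (65696), 157 (65971), 29 (67537), 33 (vehicle 41), 25 (vehicle 65966) or 31 (vehicle 78) in place of 83.

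**Figure D2:**
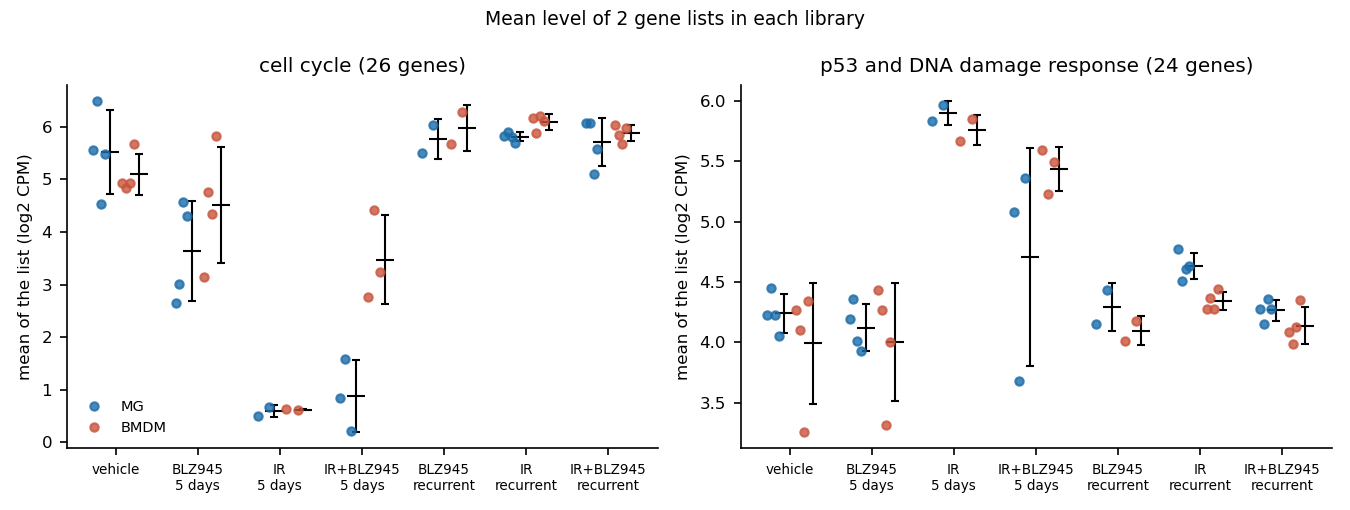
Mean log2 CPM of the 26 cell cycle genes and the 24 p53 and DNA damage genes in each library by stage, MG in blue and BMDM in red, with black marks for the mean ± SD of each group. The cell cycle list averaged 0.60 in MG and 0.62 in BMDM after 5 days of IR, against 5.52 and 5.10 in vehicle.

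In recurrence after BLZ945 (2 mice, 4 vehicle), MG carried glioma and oligodendrocyte precursor transcripts and higher MHC class II and lower microglia transcripts, and 432 genes rose and 81 fell. The protease inhibitor A2m (7.94 ± 0.98, adjusted p = 0.00061), the collagens Col11a1 (7.29 ± 1.17) and Col18a1 (7.05 ± 1.20), Hhipl2 (6.75 ± 0.97) and tenascin C (Tnc, 6.29) rose. Gpr165 (-6.24 ± 1.69), St8sia6 (-5.95), Serpinf1 (-5.02 ± 0.99) and Hpgd (-4.78 ± 0.79) fell. Csf1r fell by 1.05 ± 0.29 (adjusted p = 0.0482). Glioma and precursor genes rose for 11 of 13 (11 adjusted over the list alone, median 4.96, camera FDR = 6.21e-18), with Ncan (6.01 ± 0.99), Sox2 (5.68 ± 0.97) and Pdgfra (chromosome 5, 75151322 to 75198206; 5.53 ± 1.00, adjusted p = 0.00463). Microglia genes fell for 6 of 20 (13 adjusted over the list alone, median -1.24, camera FDR = 4.52e-14, adjusted p = 0.0942 with an estimated correlation), with Fcrls (-2.83 ± 0.56), Gpr34 (-2.68 ± 0.48) and P2ry12 (-2.47 ± 0.46). MHC class II genes rose for 5 of 10 (8 adjusted over the list alone, median 2.44, camera FDR = 1.51e-05, adjusted p = 0.437 with an estimated correlation), with H2-Ab1 (3.42 ± 0.80) and Cd74 (2.76 ± 0.76). Lars2 in these MG averaged 13.19, against 9.76 in vehicle. In place of 513 genes, 1102 passed without the doubted libraries and 11 with vehicle libraries of like Lars2 level. Leaving out 1 library gave 312 (67668), 52 (70696), 114 (vehicle 41), 255 (vehicle 65966) or 252 (vehicle 65967).

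In BMDM of the same comparison edgeR called 0 of 14568 genes, with 1183 at an unadjusted p under 0.05, 114 called by DESeq2, 43 without the doubted libraries, 4 with the Malat1 minus Lars2 term, 1 with the number style term and 2 without 70696. The glioma and precursor list had a median of 3.91, or 3.60 with bounds, and 8 of 13 genes higher adjusted over the list alone but none over all genes (camera FDR = 7.06e-11). Lars2 in these BMDM averaged 12.53.

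In recurrence after IR (4 mice, 4 vehicle), MG again carried glioma and precursor transcripts, and 610 genes rose and 20 fell. A2m (8.25 ± 0.95, adjusted p = 0.000142), Hhipl2 (7.12 ± 0.93), the lipase Pnlip (6.85) and Igfbp3 (6.69 ± 0.76, adjusted p = 0.000142) rose. Gpr165 (-4.18 ± 1.08), St8sia6 (-3.93 ± 0.86), the glutamate transporter Slc1a3 (-1.87), the transcription factor Jun (-1.36 ± 0.35) and Gal3st4 (-1.34 ± 0.25) fell. Glioma and precursor genes rose for 11 of 13 (12 adjusted over the list alone, median 5.10, camera FDR = 1.47e-22), with Sox2 (5.83 ± 0.93, adjusted p = 0.0013) and Pdgfra (5.43 ± 0.94, adjusted p = 0.00207), and the list averaged 5.10 ± 0.58 against 0.58 ± 1.07 in vehicle. Phlda3 (3.24 ± 0.44), Eda2r (3.61) and Cdkn1a (1.30 ± 0.34, adjusted p = 0.0294) rose, 3 of 24 p53 genes (3 higher and 1 lower adjusted over the list alone, camera FDR = 0.0841). Microglia genes fell for 3 of 20 (5 adjusted over the list alone, median -0.75, camera FDR = 7.24e-10, adjusted p = 0.265 with an estimated correlation), including P2ry12 (-1.27 ± 0.33). Lars2 averaged 11.89 and Malat1 8.21 in these MG, against 9.76 and 9.59 in vehicle. In place of 630 genes, 1040 passed without the doubted libraries and 1 with vehicle libraries of like Lars2 level. Single libraries moved the count to 205 (vehicle 41), 312 (vehicle 65966), 388 (vehicle 65967), 247 (68345) and 350 (68346).

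BMDM in recurrence after IR had lower antigen presentation, dendritic cell and lymphocyte transcripts and higher glioma transcripts. Here 123 genes rose and 149 fell. Ifnb1, interferon beta, held 1497 counts against 3 in vehicle (adjusted p = 0.0124), and Moxd1 (7.17 ± 1.32), the protease Mmp15 (6.52 ± 1.37) and Gpm6a (6.36 ± 1.51) rose. The granzyme Gzma (-7.79 ± 2.00), Nkg7 (-6.76 ± 1.47), Ctla4 (-5.47 ± 1.38) and Cd209a (-5.02 ± 0.72, adjusted p = 0.00294) fell. MHC class II genes fell for 8 of 10 (10 adjusted over the list alone, median -1.67, camera FDR = 1.16e-22), with H2-Ob (-2.07 ± 0.23, adjusted p = 0.000131), Cd74 (-2.18 ± 0.36) and Ciita (-2.49 ± 0.57), and their mean level was 7.90 ± 0.56 against 9.65 ± 0.29. Dendritic cell genes fell for 4 of 10 (8 adjusted over the list alone, median -3.01, camera FDR = 8.18e-16), with Ccr7 (-3.19 ± 0.48) and Flt3 (-2.95). T and NK cell genes fell for 3 of 14 (12 adjusted over the list alone, camera FDR = 1.92e-08, adjusted p = 0.15 with an estimated correlation). Glioma and precursor genes rose for 4 of 13 (12 adjusted over the list alone, median 4.51, or 4.38 with bounds, camera FDR = 9.86e-14), with Sox10 (6.05 ± 1.27) and Pdgfra (5.43 ± 1.17). Lars2 averaged 12.03 and Malat1 8.29 in these BMDM, against 6.12 and 11.87 in vehicle. The 4 recurrent mice had the Y-linked profile and 3 of the 4 vehicle mice that of Xist, and the count of 272 was 105 with a sex-linked profile term. It was 1044 without the doubted libraries and 6 with the Malat1 minus Lars2 term. Single libraries gave 78 without vehicle 41, 141 without vehicle 65966, 99 without vehicle 78, 129 without 68343, 59 without 68344, 44 without 68345 and 28 without 68346.

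In recurrence after IR+BLZ945 (4 mice, 4 vehicle), MG carried glioma and precursor transcripts and higher interferon-induced transcripts, and 297 genes rose and 404 fell. With RLE size factors 329 rose and 219 fell. A2m (6.61 ± 0.92, adjusted p = 0.00376), Hhipl2 (5.90 ± 0.90), Pnlip (5.88) and Igfbp2 (5.48 ± 0.92) rose. Gpr165 (-5.67 ± 1.19), Lgi2 (-5.33), the heat shock gene Hspa1b (-3.29 ± 0.90) and the potassium channel Kcnj2 (-3.03 ± 0.61) fell. Glioma and precursor genes rose for 8 of 13 (11 adjusted over the list alone, median 3.81, camera FDR = 9.8e-09, adjusted p = 0.187 with an estimated correlation), with Olig1 (4.14 ± 0.71, adjusted p = 0.00626) and Sox10 (4.22 ± 0.81, adjusted p = 0.00954). Interferon-induced genes rose for 5 of 24 (9 adjusted over the list alone, median 1.06, camera FDR = 6.9e-06, adjusted p = 0.53 with an estimated correlation), with Rtp4 (1.75 ± 0.44), Ifitm3 (1.60) and Ifit3 (1.52 ± 0.37). Lars2 averaged 13.97 in these MG. In place of 701 genes, 2126 passed without the doubted libraries and 0 with the Malat1 minus Lars2 term or vehicle libraries of like Lars2 level. Removing 1 library gave 425 (67169), 194 (67543), 53 (67947), 349 (68362), 155 (vehicle 41), 271 (vehicle 65966), 73 (vehicle 65967) or 1245 (vehicle 78).

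BMDM of that comparison had 4 genes higher and 0 lower: Lars2 (5.60 ± 0.98), the metallothionein Mt2 (3.64 ± 0.62), Tatdn2 (2.55 ± 0.45) and the calpain subunit Capns1 (1.83 ± 0.30), each at an adjusted p of 0.0476. At an unadjusted p under 0.05 there were 1504 genes, DESeq2 called 229, and 92 passed without the doubted libraries. No gene passed with RLE size factors, with the sex-linked profile term, or without any 1 of the 4 vehicle libraries, 67169 or 67543. The count was 1 without 67947, 11 without 68362 and 2 without the low-count filter. The glioma and precursor list had a median of 3.53, or 3.48 with bounds, and 10 of 13 genes higher adjusted over the list alone but none over all genes (camera FDR = 2.86e-09).

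**Figure D3:**
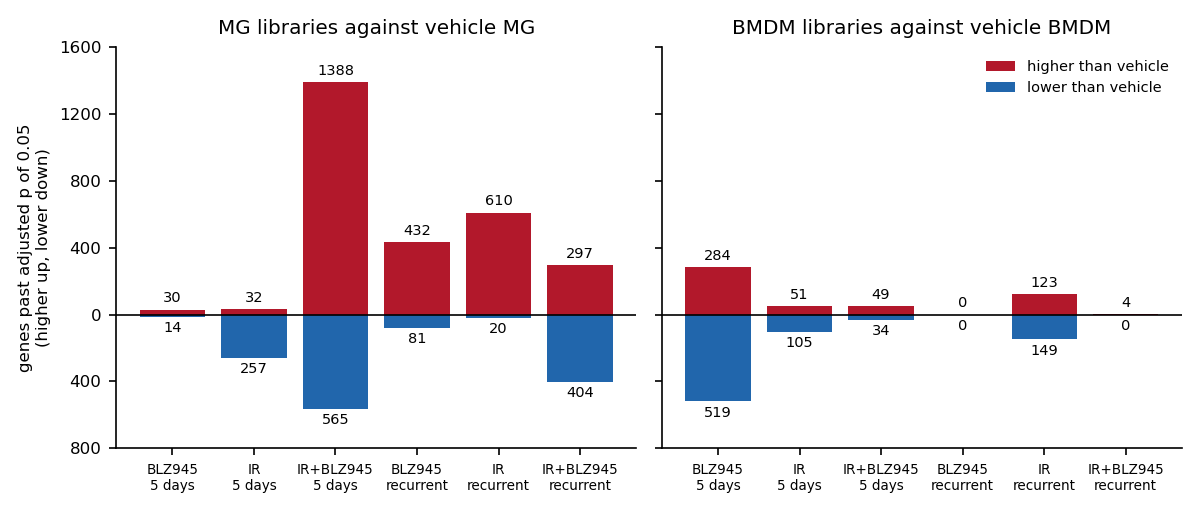
Bars from 0 give the number of genes higher and lower than vehicle after each treatment, past an adjusted p of 0.05, MG and BMDM in separate panels. Counts in MG ran from 44 to 1953 and in BMDM from 0 to 803.

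Recurrent tumours were next set against tumours at 5 days of the same treatment, comparisons of regrowth with early response. After BLZ945 (2 recurrent, 4 at 5 days), MG in recurrence had higher glioma, cell cycle and hypoxia transcripts, and 918 genes rose and 279 fell. Olig2 (at least 497-fold) and Pdgfra (10.20 ± 1.32) were higher, and Rtn4rl1 (-5.08) lower. Arg1, arginase 1, rose by 8.30 ± 1.69 (adjusted p = 0.00408) and Csf1r fell by 1.20 ± 0.29 (adjusted p = 0.0136). Rises were seen in 11 of 13 glioma genes (12 adjusted over the list alone, median 7.53, or 7.05 with bounds, camera FDR = 3.36e-18), 12 of 26 cell cycle genes (20, median 2.16, camera FDR = 1.14e-10) and 9 of 20 hypoxia genes (16, camera FDR = 4.2e-09), among them Adm (6.15 ± 0.88) and Vegfa (3.06 ± 0.75). With an estimated correlation the cell cycle and hypoxia lists had adjusted p = 0.207 each. In place of 1197 genes, 2383 passed without the doubted libraries, 673 with the number style term and 219 with the Malat1 minus Lars2 term. Leaving out 122 gave 639, 124 709, 67668 651 and 70696 735.

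In BMDM, recurrence after BLZ945 came with higher complement, hypoxia and microglia transcripts and lower dendritic cell and MHC class II transcripts than at 5 days, and 753 genes rose and 240 fell. Fcna (at least 236-fold) and Col18a1 (at least 164-fold) were higher, and Cd209a (-6.80 ± 1.07, adjusted p = 0.00116) and Lyz1 (-5.94) lower. Csf1r (1.44 ± 0.35, adjusted p = 0.0185), Igf1 (2.41 ± 0.51, adjusted p = 0.00805) and Arg1 (6.22 ± 1.74, adjusted p = 0.0345) rose. Complement and Fc receptor genes rose for 12 of 15 and fell for 1 (14 and 1 adjusted over the list alone, camera FDR = 5.51e-09), with C1qa (2.36 ± 0.47), hypoxia genes for 10 of 20 (17, camera FDR = 3.67e-12), with Bnip3 (3.06 ± 0.62), and microglia genes for 8 of 20 (9, camera FDR = 6.48e-07), with Tmem119 (3.02 ± 0.58). With an estimated correlation these had adjusted p = 0.059, 0.059 and 0.122. Glioma genes rose for 7 of 13 (12 adjusted over the list alone, median 5.02, or 4.51 with bounds, camera FDR = 3.67e-10). MHC class II genes fell for 3 of 10 (9 adjusted over the list alone, camera FDR = 3.25e-14), with H2-Oa (-2.53 ± 0.45, adjusted p = 0.00336), and dendritic cell genes for 4 of 10 (6, camera FDR = 6.35e-11). In place of 993 genes, 887 passed without the doubted libraries and 315 with the number style term. The count was 119 without 67668 and 366 without 70696.

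After IR (4 recurrent, 2 at 5 days), MG in recurrence had higher cell cycle, glioma and interferon-induced transcripts and lower p53 targets, and 1182 genes rose and 498 fell. Of 26 cell cycle genes 24 rose (26 adjusted over the list alone, median 5.84, camera FDR = 6.12e-30), with Mki67 (6.92 ± 1.16, adjusted p = 0.00128), Top2a (8.30 ± 1.53) and Nek2 (at least 185-fold). Of 24 p53 genes 10 fell (13 adjusted over the list alone, median -1.46, camera FDR = 1.02e-11), with Cdkn1a (-2.52 ± 0.39, adjusted p = 0.000916) and Phlda3 (-2.33 ± 0.46). Glioma genes rose for 11 of 13 (13 adjusted over the list alone, median 6.59, or 5.41 with bounds, camera FDR = 6.95e-12), with Olig2 (at least 257-fold). Interferon-induced genes rose for 12 of 24 (17 adjusted over the list alone, median 2.35, camera FDR = 5.47e-10, adjusted p = 0.33 with an estimated correlation), with Rsad2 (3.64 ± 0.70) and Isg15 (2.83 ± 0.54). Gpr165 (-5.20), Lyve1 (-4.76 ± 1.12) and Matn1 (-3.99) fell. In place of 1680 genes, 1796 passed without the doubted libraries and 165 with the Malat1 minus Lars2 term. The count was 565 without 65698, 358 without 65972, 1108 without 68343 and 1015 without 68345.

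In BMDM 1029 genes rose and 799 fell from 5 days of IR to recurrence. The cell cycle list rose for 24 of 26 genes (25 adjusted over the list alone, median 5.10, camera FDR = 4.73e-33), with Birc5 (at least 598-fold, adjusted p = 4.11e-08), Prc1 (at least 591-fold) and Mki67 (3.09 ± 1.02, adjusted p = 0.0489). The p53 list fell for 10 of 24 (11 adjusted over the list alone, camera FDR = 3.03e-12), with Cdkn1a (-2.43 ± 0.34, adjusted p = 0.000146) and Phlda3 (-4.01 ± 0.78). Glioma genes rose for 7 of 13 (10 adjusted over the list alone, median 5.12, or 4.99 with bounds, camera FDR = 1.85e-05), while MHC class II genes fell for 5 of 10 (6, camera FDR = 3.63e-09), with H2-Ab1 (-2.71 ± 0.44), and immediate early genes for 10 of 18 (11, camera FDR = 3.98e-07), with Dusp1 (-3.74 ± 0.58). These last 3 lists had adjusted p = 0.0536 each with an estimated correlation. Cd209a (-7.85 ± 0.84, adjusted p = 1.14e-05) and Mrc1 (-3.19 ± 0.68, adjusted p = 0.0051) fell and Arg1 rose (7.76 ± 2.49, adjusted p = 0.0447). In place of 1828 genes, 1283 passed without the doubted libraries and 37 with the Malat1 minus Lars2 term. Leaving out 65698 gave 400, 68343 1174, 68345 1197 and 68346 1143.

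After IR+BLZ945 (4 recurrent, 3 at 5 days), MG in recurrence had higher cell cycle and hypoxia transcripts, and 1665 genes rose and 2412 fell. Cell cycle genes rose for 22 of 26 (24 adjusted over the list alone, median 4.13, camera FDR = 1.65e-24, adjusted p = 0.213 with an estimated correlation), with Ccnb1 (8.46 ± 0.93, adjusted p = 2.56e-05) and Mki67 (2.59 ± 0.76, adjusted p = 0.0162). Hypoxia genes rose for 13 of 20 (13 adjusted over the list alone, camera FDR = 2.83e-05, adjusted p = 0.725 with an estimated correlation), with Adm (7.56 ± 1.11). The p53 list fell for 7 of 24 and rose for 1 (13 and 1 adjusted over the list alone, camera FDR = 0.000957, adjusted p = 0.213 with an estimated correlation), with Cdkn1a (-2.04 ± 0.36, adjusted p = 0.00111). Glioma genes rose for 5 of 13 (6 adjusted over the list alone, median 1.77, camera FDR = 0.00242, adjusted p = 0.725 with an estimated correlation). Fam64a (at least 144-fold) and Ifnb1 (at least 90.4-fold) were higher, and Kl (at least 304-fold) and Emr4 (at least 121-fold) lower. Igf1 fell (-2.38 ± 0.74, adjusted p = 0.0213) and Arg1 rose (4.95 ± 1.61, adjusted p = 0.0266). Ttr averaged 7.43 ± 4.07 in the 5-day MG. The count of 4077 was 3581 without the doubted libraries and 158 with the Malat1 minus Lars2 term.

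In BMDM, recurrence after IR+BLZ945 differed from 5 days by 259 higher and 279 lower genes. Cell cycle genes rose for 13 of 26 (20 adjusted over the list alone, median 1.99, camera FDR = 6.79e-25), with Tk1 (3.16 ± 0.39, adjusted p = 0.000144), hypoxia genes for 10 of 20 (16, camera FDR = 1.56e-13), with Bnip3 (2.88), and microglia genes for 4 of 20 (9, camera FDR = 2.29e-09), with Tmem119 (3.26 ± 0.60). Glioma genes rose for 5 of 13 (6 adjusted over the list alone, camera FDR = 1.78e-06). The p53 list fell for 7 of 24 (12 adjusted over the list alone, camera FDR = 1.66e-10), with Phlda3 (-3.98 ± 0.74) and Cdkn1a (-1.41 ± 0.31, adjusted p = 0.0135), and dendritic cell genes for 6 of 10 (8, camera FDR = 4.61e-17), with Cd209a (-6.20 ± 0.77). Csf1r rose (1.51 ± 0.34, adjusted p = 0.0152). The nitric oxide synthase Nos2 was at least 215-fold higher, Col14a1 rose by 7.76 ± 1.56, and Cd209f (at least 296-fold) and Tuba8 (-8.15) were lower. In place of 538 genes, 1661 passed without the doubted libraries and 196 with the Malat1 minus Lars2 term. The count was 189 without 65696, 203 without 67169, 161 without 67537, 248 without 67543 and 298 without 67947.

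The combination was then set against each single treatment. At 5 days, IR+BLZ945 (3 mice) against IR (2 mice) in MG had 8 genes higher and 25 lower, or 8 and 15 with RLE size factors. Enpp2 was higher (7.56 ± 1.60, adjusted p = 0.0495), and P2ry12 (-2.89 ± 0.43, adjusted p = 0.0149), Siglech (-2.16 ± 0.43), Tgif2 (-4.56 ± 0.72) and Lyve1 (at least 73.4-fold) were lower. Those 2 microglia genes fell among 20 (14 adjusted over the list alone, median -1.19, camera FDR = 4.64e-11, adjusted p = 0.204 with an estimated correlation). In place of 33 genes, 1235 passed by DESeq2 and 323 without the doubted libraries. The count was 0 without 65696 or 65972, 215 without 65971, 575 without 67537 and 142 without 65698.

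In BMDM that comparison had 183 genes higher and 161 lower, with higher cell cycle and lower border-associated macrophage transcripts. Cell cycle genes rose for 12 of 26 (17 higher and 1 lower adjusted over the list alone, median 2.44 with bounds, camera FDR = 1.6e-12, adjusted p = 0.136 with an estimated correlation), with Birc5 (at least 84.1-fold) and Cdc20 (7.47 ± 1.27). In the same libraries 2 of 10 dendritic cell genes were higher (6 adjusted over the list alone, camera FDR = 4.23e-05, mean 7.42 against 4.62) and 1 of 8 Ly6C-high monocyte genes (3, camera FDR = 0.0176, mean 4.17 against 0.98), with adjusted p = 0.174 and 0.222 with an estimated correlation. The B cell list stood at 4.27 against 0.60 and the neutrophil list at 1.56 against -1.23 (camera FDR = 0.0928 and 0.213). Border-associated genes fell for 4 of 10 (9 adjusted over the list alone, camera FDR = 3.36e-09), with the complement receptor Vsig4 (at least 209-fold lower) and Mrc1 (-3.39 ± 0.75, adjusted p = 0.0221). Ttr (at least 1914-fold, adjusted p = 0.0445) and Serpinb1a (at least 190-fold) were higher and Epor (-7.06 ± 1.24) and P2ry12 (-3.49 ± 0.56) lower. In place of 344 genes, 305 passed without the doubted libraries and 41 with the Malat1 minus Lars2 term. Leaving out 65696 gave 100, 65698 44 and 65972 1369.

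At 5 days, IR+BLZ945 (3 mice) against BLZ945 (4 mice) in MG had 1021 genes higher and 409 lower. P53 genes rose for 8 of 24 (8 higher and 1 lower adjusted over the list alone, camera FDR = 3.97e-05, adjusted p = 0.139 with an estimated correlation), with Phlda3 (5.74 ± 0.50, adjusted p = 2e-06), Eda2r (5.79) and Cdkn1a (3.58 ± 0.38, adjusted p = 3.78e-05). Cell cycle genes fell for 14 of 26 (17 adjusted over the list alone, median -2.54, camera FDR = 3.92e-13, adjusted p = 0.168 with an estimated correlation), with Tk1 (-5.63 ± 0.86), and MHC class II genes for 6 of 10 (8, camera FDR = 0.000336, adjusted p = 0.297 with an estimated correlation), with Cd74 (-2.96 ± 0.77). Csf1r fell (-0.81 ± 0.25, adjusted p = 0.0457). S100a9 (at least 224-fold) and Enpp2 (9.90 ± 1.32) were higher, Dtl (-6.21) lower, and Ttr held 18159 counts against 3. Astrocyte genes rose for 6 of 10 (8 adjusted over the list alone, camera FDR = 3.12e-07, adjusted p = 0.164 with an estimated correlation), with Clu (5.97). In place of 1430 genes, 927 passed without the doubted libraries and 145 with the number style term. The count was 419 without 122, 297 without 124, 946 without 65971 and 2240 without 67537.

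In BMDM the same comparison had 438 genes higher and 83 lower. P53 genes rose for 6 of 24 (10 adjusted over the list alone, camera FDR = 1.68e-05), with Phlda3 (4.13 ± 0.75), Ccng1 (1.79 ± 0.29), Cdkn1a (1.19 ± 0.31, adjusted p = 0.0362) and Eda2r (at least 53.8-fold). Cell cycle genes fell for 4 of 26 (6 adjusted over the list alone, camera FDR = 4.99e-12, adjusted p = 0.123 with an estimated correlation), with Tk1 (-2.53 ± 0.38). The growth factor Igf1 rose (1.90 ± 0.47, adjusted p = 0.03), Nov was at least 621-fold and Cd209f at least 272-fold higher, and Fkbp5 (-3.04 ± 0.63) and the kinesin Kif4 (-2.89) fell. The astrocyte list rose for 4 of 10 (9 adjusted over the list alone, camera FDR = 4.93e-06). In place of 521 genes, 338 passed without the doubted libraries and 165 with the number style term. Leaving out 122 gave 332 and 65975 941.

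In recurrence, edgeR called 0 genes for IR+BLZ945 against IR (4 mice each) in both populations. In MG 2062 genes had an unadjusted p under 0.05 and DESeq2 called 531, and in BMDM 241 and 13, and 0 passed in both without the doubted libraries. The BMDM had higher MHC class II transcripts after the combination by the list test, with all 10 genes higher adjusted over the list alone, a median of 1.20 and a camera FDR of 8.38e-40, at mean levels of 9.08 ± 0.45 against 7.90 ± 0.56. In MG the list was higher too (8 adjusted over the list alone, median 1.95, camera FDR = 1.1e-09, adjusted p = 0.374 with an estimated correlation), at 6.71 ± 0.86 against 4.85 ± 0.46. In BMDM the list test also called the dendritic cell list (2 of 10 higher adjusted over the list alone, median 1.62, camera FDR = 8.16e-17) and the glioma list (0 of 13 lower, median -1.29, camera FDR = 2.59e-09). For recurrent IR+BLZ945 against recurrent BLZ945 (4 and 2 mice) edgeR called 0 genes, with 687 at an unadjusted p under 0.05 and 28 by DESeq2 in MG and 58 and 2 in BMDM. Without the doubted libraries 2 passed in MG and 0 in BMDM, and in MG 2 passed without 67543 and 1 without 67668. In the simulation of recurrent IR+BLZ945 against recurrent IR, on 14063 genes in MG, 64.2% of genes changed 4-fold were recovered, and in BMDM, on 14103 genes, 44.8%.

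**Figure D4:**
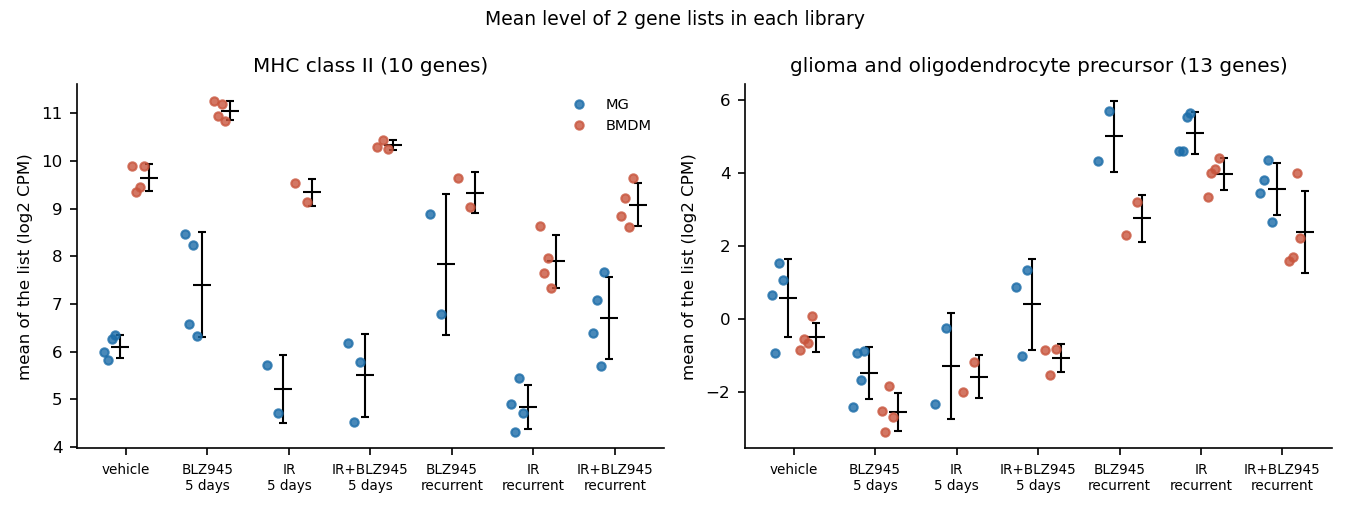
Mean log2 CPM of the 10 MHC class II genes and the 13 glioma and oligodendrocyte precursor genes in each library by stage, MG in blue and BMDM in red, with black marks for the mean ± SD of each group. MHC class II in BMDM averaged 11.06 after 5 days of BLZ945, 9.65 in vehicle and 7.90 in recurrence after IR.

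Differences between the populations in their response were tested as interactions over all 46 libraries. The response to 5 days of BLZ945 was higher in MG than in BMDM for 205 genes and lower for 58. Mfsd9 (9.72 ± 1.37, adjusted p = 0.000103) and the potassium channel Kcnma1 (8.46) had the largest positive differences and Wnt11 (-6.34 ± 1.31) and Krt80 (-6.18) the largest negative ones. The lipid transport genes Apoe (3.36 ± 0.76, adjusted p = 0.0118) and Abca1 (2.76 ± 0.54) passed among 11 lipid efflux genes (3 adjusted over the list alone, camera FDR = 0.00262, adjusted p = 0.172 with an estimated correlation). Csf1r did not pass (1.20 ± 0.38, adjusted p = 0.0994). With the mouse as a block the camera call of the matrix list was lost (adjusted p from 0.0168 to 0.0728). In place of 263 genes, 200 passed without the doubted libraries. The count was 161 without mouse 122, 663 without 65975, 132 without 41, 127 without 65966 and 157 without 78.

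The response to 5 days of IR differed for 12 genes, 11 higher in MG, with the serine protease inhibitor Serpinb1a (9.78 ± 1.91, adjusted p = 0.0285), Fut10 (8.31) and the condensin subunit Ncapd2 (7.28 ± 1.37) higher and the lysosomal Hgsnat (-2.92 ± 0.55, adjusted p = 0.0221) lower. DESeq2 called 291, and 82 passed without the doubted libraries. The count was 0 without 65698, 456 without 65972, 1 without 41 or 78, 3 without 65966 and 95 without 65967. The response to 5 days of IR+BLZ945 was higher in MG for 9 genes, with Cdh17 (8.36 ± 1.89) and Lpar6 (2.63 ± 0.50), and lower for 48, with Klrd1 (-8.80), Ube2c (-7.94 ± 1.38, adjusted p = 0.00588), Ccnb1 (-6.54 ± 1.11) and Aurkb (-5.46). Cell cycle genes were lower for 6 of 26 (18 adjusted over the list alone, median -3.10, camera FDR = 1.43e-17, adjusted p = 0.19 with an estimated correlation). With the mouse as a block, camera calls were gained at 5 days of IR for MHC class I (adjusted p from 0.105 to 0.0248), immediate early (0.0562 to 0.0245), T and NK cell (0.079 to 0.0237) and neutrophil genes (0.0803 to 0.0143), and at 5 days of IR+BLZ945 for microglia (0.0517 to 0.023), hypoxia (0.0502 to 0.0093) and matrix genes (0.0502 to 0.027). For 5 days of IR+BLZ945, the count of 57 was 106 without the doubted libraries. It was 34 without mouse 65696, 31 without 65971, 16 without 41, 13 without 65966 and 22 without 78.

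In recurrence after IR the response was higher in MG for 3 genes, among them Cd200 (6.06 ± 0.98, adjusted p = 0.00436), the ligand of an inhibitory receptor of macrophages, and cyclin D2 (Ccnd2, 3.86 ± 0.73, adjusted p = 0.0355). With the mouse as a block 0 passed, while DESeq2 called 65, and 24 passed without the doubted libraries. The count was 0 without 41, 65966 or 68346, 1 without 68344 or 68345 and 6 without 65967. Dendritic cell genes (median 1.86, 3 of 10 higher adjusted over the list alone, camera FDR = 4.32e-09) were higher by the list test. In recurrence after BLZ945 edgeR called 0 genes, with 478 at an unadjusted p under 0.05, 24 by DESeq2 and 4 without the doubted libraries. There the response of the microglia list was lower in MG (median -1.60, 0 of 20 adjusted over the list alone, camera FDR = 5.45e-17) and that of MHC class II higher (median 2.76, 7 of 10, camera FDR = 5.45e-17). In recurrence after IR+BLZ945 edgeR called 0 genes, with 518 at an unadjusted p under 0.05, 21 by DESeq2 and 3 without the doubted libraries. With the mouse as a block, the camera call of alternative activation was gained in recurrence after BLZ945 (adjusted p from 0.0583 to 0.0208), and in recurrence after IR+BLZ945 that of matrix genes was gained (0.057 to 0.0421) and that of lipid efflux lost (0.0474 to 0.056).

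The identity gap between MG and BMDM of the same mouse was 6.46 ± 1.04 in vehicle (n = 4), 9.07 ± 1.03 after 5 days of BLZ945 (n = 4), 7.50 ± 2.36 after IR (n = 2, including 65698, whose sex-linked profiles did not match) and 7.34 ± 2.06 after IR+BLZ945 (n = 3). Leaving out 1 mouse turned the direction of these last 2 against vehicle. In recurrence it was 3.83 ± 0.43 after BLZ945 (n = 2), 4.36 ± 0.69 after IR (n = 4) and 5.25 ± 0.39 after IR+BLZ945 (n = 4). By two-sided exact permutation tests against vehicle, p = 0.0286 after 5 days of BLZ945, the smallest that 4 against 4 mice allow, and 0.129 after adjustment over the 6 tests. The exact p was 0.467 for 5-day IR and 0.0667 for recurrent BLZ945, where 0.0667 is the smallest possible, 0.571 for 5-day IR+BLZ945, 0.0571 for recurrent IR and 0.0857 for recurrent IR+BLZ945. Adjusted values were 0.56, 0.129, 0.571, 0.129 and 0.129, so no stage passed.

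**Figure D5:**
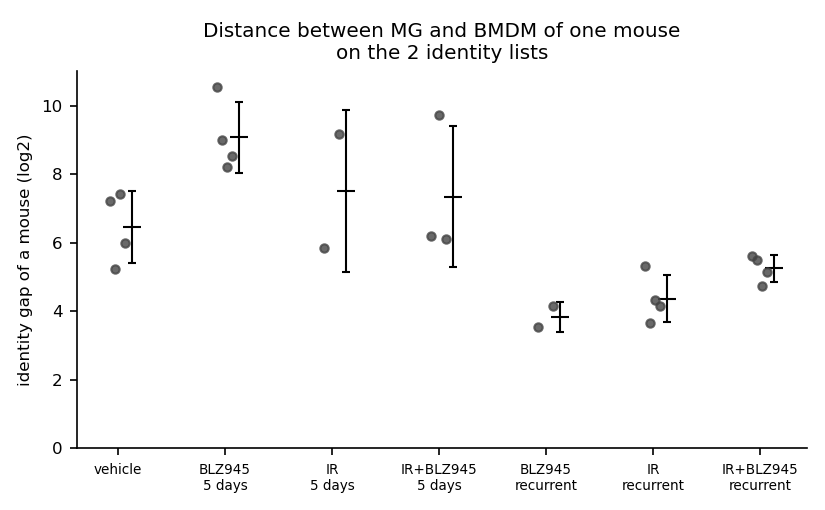
Identity gap (log2, defined above) of each mouse by stage, with black marks for the mean ± SD. The gap averaged 6.46 in vehicle and 9.07 after 5 days of BLZ945.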

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

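The tests of carried-over tumour RNA, of a response shared by the treated mice and of different library preparations were chosen after the patterns were seen. So were the comparisons with vehicle libraries of like Lars2 level. The counts of other splits were planned.

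Of 164 groups of 4 mice tested for a library far from the other 3, 9 had one, where chance flags about 1 in 20, or 8.2 groups. Itga4 was lowest in BMDM of 124 (5.98, nearest 6.88) and in MG of 65975 (1.02, nearest 1.75), both after 5 days of BLZ945. The neuron list was highest in MG of 123 (-0.93, nearest -2.24). Mki67 was highest in BMDM of 68346 in recurrence after IR (6.67, nearest 6.19) and in MG of 67169 in recurrence after IR+BLZ945 (6.38, nearest 5.22). Csf1r was lowest in MG of 68362 (12.29, nearest 12.48). In vehicle BMDM, Igf1 was lowest in 41 (5.36, nearest 6.38), Arg1 lowest in 65967 (3.34, nearest 8.31) and Malat1 highest in 65967 (13.2, nearest 11.51). Interaction tests of MG against BMDM called 263 genes for 5-day BLZ945, 12 for IR, 57 for IR+BLZ945 and 3 for recurrent IR.

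Glioma and oligodendrocyte precursor transcripts were higher in MG of all recurrent groups (camera FDR = 1.47e-22 after IR), with Pdgfra at 6.81, 7.01 and 5.18 in MG and 4.42, 5.95 and 3.49 in BMDM after BLZ945, IR and IR+BLZ945, although the CD45+CD11b+ gate should remove tumour cells. RNA of tumour cells carried into both sorts may be a source: over the 10 recurrent mice the list's level in MG and in BMDM correlated (Pearson r = 0.738, permutation p = 0.0163, Spearman rho = 0.745, permutation p = 0.0177; r = 0.853 without 68362 and 70696). Centred on group means r was 0.635, and this was the only relation of its kind computed. Against vehicle MG of like Lars2 level the medians were 4.96, 5.1 and 3.9 (4.96, 5.10 and 3.81 against all), which counts against a different make-up of the RNA, but with fewer libraries only 1, 0 and 0 of 13 genes passed, short of the 5 set for excluding it, and it cannot be told apart. Expression by the sorted cells themselves, with the stage as its cause, was not tested.

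Choroid plexus transcripts, led by Ttr and Enpp2, were high in both libraries of the 5-day IR+BLZ945 mice 65696 and 67537. Choroid plexus cells of single mice could be the source, although the gate should remove them: 3 of 18 markers (16.7%, exact 95% interval 3.6 to 41.4) were higher in each of these 4 libraries than in the other 42, with 8 at the floor. That share met the bound set for excluding this source, but a rule that the whole interval lie below it was applied after the value was seen, and the source cannot be told apart. Ttr held 9171 and 8966 counts in MG and 3510 and 2997 in BMDM of these mice, against 22 and 69 in mouse 65971. A response shared by the treated mice cannot be told apart either, since the mean marker level of 65971 differed by -0.02 from the lower of theirs in BMDM but stood at -0.53 against 1.90 and 2.07 in MG, between the bounds set.

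Lars2 was higher and Malat1 lower in the recurrent libraries of both populations. A difference between library preparations may contribute. Among 26 other libraries only MG of the vehicle mice 41 and 78 lay in the recurrent range of Malat1 minus Lars2 (-6.33 to -0.63). Their BMDM lay outside it. Gene length was argued against for recurrent against 5-day IR (Spearman rho across genes, which are not independent replicates, -0.121 in MG and 0.062 in BMDM), but it stays open in MG after IR+BLZ945 (-0.305, and -0.36 against vehicle). Reads of annotated ribosomal RNAs were argued against, since the longest stretch any of 356 shared with 9 Lars2 transcripts was 16 bases; the test's wording was narrowed to annotated RNAs after its value was seen, and the large cytosolic ribosomal RNA was not among them (its precursor Rn45s, looked up afterwards, averaged 9.55 in vehicle BMDM, 11.04, 11.47 and 11.50 in recurrence and 13.06 after 5 days of BLZ945, where Lars2 averaged 7.90). The stage of the tumour stays open too and was not tested apart.

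For each comparison of at least 3 mice per group, 35 splits of the same libraries were compared, the real one included. Only the real split of 35 gave as many genes in the next comparisons, the smallest share possible and unadjusted. A batch following the groups would give it too. Against vehicle they were 5-day BLZ945 in BMDM (803, 227) and 5-day IR+BLZ945 in MG (1953, 640) and BMDM (83, 22). Recurrent IR in MG (630, 0) and BMDM (272, 0) and recurrent IR+BLZ945 in MG (701, 0) and BMDM (4, 0) followed. The 4 became 0 in 6 of 8 fits without 1 library, with RLE size factors or with the sex-linked profile term. Next were recurrent against 5-day IR+BLZ945 in MG (4077, 7) and BMDM (538, 77) and 5-day IR+BLZ945 against BLZ945 in MG (1430, 796). The split with 796 set 122, 123 and 124 apart, and 145 passed with the number style term. Last were the differences in response to 5-day BLZ945 (263, 175), 5-day IR+BLZ945 (57, 2) and recurrent IR (3, 0). The 3 became 0 with the mouse as a block. For MG against BMDM (1454) 1 of 35 splits gave as many (highest other 234). Libraries are paired by mouse, and only 8 splits part every pair (1 as large, highest other 61), too few for a share under 0.05. Chance could not be excluded for 5-day BLZ945 in MG, where 3 of 35 splits gave as many as the real 44. The highest, with 960, many times the real count, set 122, 123, 124 and vehicle 65967 apart, which points to a structure of the samples. The same split gave the 227 in BMDM and the 175 in the response, so it may enter those counts too. Both sides mix short and long mouse numbers, and what the split follows was not identified. In 5-day IR+BLZ945 against BLZ945 in BMDM, 2 of 35 gave as many as the real 521; the highest other (798) set the short numbers 122, 123 and 124 apart, and 165 passed with the number style term. All 35 gave 0 genes for recurrent IR+BLZ945 against recurrent IR in MG and in BMDM and for the difference in response to recurrent IR+BLZ945.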

How the results depend on the processing

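The settings named above as chosen after seeing the data were unplanned, and the others planned. The cause of a moved count was not tested, except that fewer libraries enter where some were left out. Recurrent libraries differ from most others in Malat1 minus Lars2, so that term also takes up part of the difference between stages. Moved means at least 1.5-fold. DESeq2 raised all 33 counts and moved 30, RLE size factors left 31 unmoved and no low-count filter 29. List calls of 957 were 390 with the preset, 58 with an estimated correlation and 211 with fry. RLE size factors shifted the median log2 fold change of all genes by 0.11 in recurrent IR+BLZ945 MG, -0.11 in recurrent against 5-day BLZ945 BMDM, and 0.11, 0.15 and 0.11 in the responses to 5-day IR+BLZ945, recurrent BLZ945 and recurrent IR. Whether more genes rose or fell turned under at least 1 setting for, among others, 5-day BLZ945 (MG), 5-day IR+BLZ945 (both populations), recurrent IR (BMDM) and recurrent IR+BLZ945 (MG) against vehicle, and 5-day IR+BLZ945 against IR. Of 203 list tests with the mouse as a block, 13 calls changed, all given with their results. The block moved only the gene count for the response to recurrent IR, from 3 to 0. In the simulation of 5-day IR against vehicle in BMDM, on 14089 genes, 29.9% of genes changed 4-fold were recovered at the depth and number of mice of the data, neither of which was varied.

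Values follow the order of the report: 5-day and then recurrent BLZ945, IR and IR+BLZ945; and for the combination, against IR at 5 days and in recurrence, then against BLZ945 likewise. DESeq2 called 2023 genes for MG against BMDM. Against vehicle it called 556, 830, 2772, 910, 956 and 1698 in MG and 1805, 1120, 610, 114, 961 and 229 in BMDM. In recurrence against 5 days it called 2019, 2875 and 4803 in MG and 1616, 3321 and 1180 in BMDM. For the combination it called 1235, 531, 2345 and 28 in MG and 1867, 13, 1232 and 2 in BMDM, and for the responses 694, 291, 335, 24, 65 and 21. Without doubted libraries 2686 passed for MG against BMDM, 454, 298, 1153, 1102, 1040 and 2126 in MG and 369, 249, 824, 43, 1044 and 92 in BMDM against vehicle, 2383, 1796 and 3581 in MG and 887, 1283 and 1661 in BMDM in recurrence against 5 days, 323, 0, 927 and 2 in MG and 305, 0, 338 and 0 in BMDM for the combination, and 200, 82, 106, 4, 24 and 3 for the responses. With the Malat1 minus Lars2 term 1038 passed for MG against BMDM, 0, 84, 1178, 322, 374 and 0 in MG and 710, 67, 119, 4, 6 and 2 in BMDM against vehicle, 219, 165 and 158 in MG and 541, 37 and 196 in BMDM in recurrence, 29, 0, 1243 and 0 in MG and 41, 0, 523 and 0 in BMDM for the combination, and 141, 7, 26, 0, 3 and 0 for the responses.

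Vehicle libraries of like Lars2 level gave 343 for MG against BMDM and 0, 74, 214, 11, 1 and 0 in MG against vehicle. RLE size factors moved recurrent IR+BLZ945 in BMDM to 0 and the response to recurrent IR to 5. No low-count filter gave 2 for recurrent IR+BLZ945 in BMDM, 222 for 5-day IR+BLZ945 against IR in BMDM, and 6 and 37 for the responses to 5-day IR and IR+BLZ945. With the sex-linked profile term the moved counts were 7 and 1132 in MG (5-day BLZ945, 5-day IR+BLZ945), 93, 105 and 0 in BMDM (5-day IR, recurrent IR, recurrent IR+BLZ945), 260 (recurrent against 5-day IR+BLZ945, BMDM), 737 and 298 (5-day IR+BLZ945 against BLZ945, MG and BMDM), and 7 and 5 (responses to 5-day and recurrent IR). The number style term gave 3, 145 and 1171 in MG at 5 days, 267 and 1 in BMDM (5-day IR+BLZ945, recurrent BLZ945), 673 and 315 (recurrent against 5-day BLZ945, MG and BMDM) and 145 and 165 (5-day IR+BLZ945 against BLZ945). One fit over all libraries gave, in MG, 93 and 1098 (5-day BLZ945, 5-day IR+BLZ945) and 202, 289 and 167 in recurrence, and in BMDM 1500, 641 and 271 at 5 days and 628 and 58 (recurrent IR, recurrent IR+BLZ945). It also gave 1095 (recurrent against 5-day IR, MG), 850 (IR+BLZ945, BMDM), 21 and 1142 (5-day IR+BLZ945 against IR) and 748 and 1302 (against BLZ945).

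Leaving out 1 library at a time gave 773 to 1084 genes for MG against BMDM. Against vehicle, the ranges were 1 to 695, 15 to 862, 382 to 2619, 52 to 492, 205 to 524 and 53 to 1245 in MG and 462 to 1650, 49 to 1150, 17 to 157, 0 to 2, 28 to 187 and 0 to 11 in BMDM. In recurrence they were 639 to 1649, 358 to 1351 and 2879 to 3944 in MG and 119 to 1410, 400 to 2065 and 161 to 543 in BMDM. For the combination they were 0 to 575, 0, 297 to 2240 and 0 to 2 in MG and 44 to 1369, 0, 332 to 941 and 0 in BMDM, and for the responses 127 to 663, 0 to 456, 13 to 50, 0, 0 to 6 and 0. The change of the identity gap ran from 2.13 to 2.94, -0.63 to 2.71 and -0.3 to 1.51 at 5 days and from -3.04 to -2.3, -2.51 to -1.77 and -1.62 to -0.89 in recurrence, and it was -0.3 in place of 0.89 for 5-day IR+BLZ945 without the doubted libraries.

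Of the gene values under other settings 14056 kept their direction and side of the threshold, 4442 kept the direction but no longer passed, 44 passed newly, 209 that had not passed changed sign and 23 reversed; the cause of the reversals was not tested. Of the reversed, 17 did so with the Malat1 minus Lars2 term. These were Csf2ra (0.02), Dusp1 (0.77), Cd209f (2.48) and Cspg4 (-0.39) in recurrent IR against vehicle in BMDM, and Cd209g (0.98), Tgfbi (-0.85), Itgam (-0.15), Csf2rb2 (-0.3), Gapdh (-0.66), Cxcl10 (-0.78), Psme1 (-0.37), Bin1 (-0.34), Aldoc (0.23) and Sc4mol (0.48) in recurrent against 5-day IR in BMDM. The others were C1qa (-0.37) and Ltc4s (-0.13) in MG and Gapdh (-0.03) in BMDM in recurrent against 5-day IR+BLZ945. Without the doubted libraries Ms4a1 reversed in 5-day IR+BLZ945 MG (-3.78 against vehicle, -4.98 against BLZ945) and in recurrent against 5-day IR+BLZ945 (3.01). Without 5-day IR BMDM of 65972, C4b (1.08, lowest -3.05) and Prf1, recurrent IR against 5-day IR in BMDM (2.2, lowest -9.35), and C4b in 5-day IR+BLZ945 against IR (0.25, lowest -3.88) reversed.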
